A study of Mus musculus with 13 samples.

How the data were processed

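Fecal pellets of 12 female C57BL/6 mice and 1 library labelled Standard were profiled by amplicons of the V3/V4 regions of the 16S ribosomal RNA gene. The deposited table holds counts of reads per amplicon sequence variant (ASV) and library, from which the authors had removed chimeric sequences, per the name of the table. The tool and version that made it, the classifier and the taxonomic reference are not given in the sources used here. A deposited table of taxonomic names and a deposited table of groups came with it, and the groups matched those read from the library titles for all 13 libraries. Titles held letters for age group and treatment, the ages of 12 and 72 weeks came from the description of the series, and replicate numbers were given in the order of the accessions.

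Of 2798 deposited ASVs, 2658 were kept as bacterial or archaeal and neither chloroplast nor mitochondrial, 2411 of them in fecal libraries. These held 360038 of the fecal reads, of which 83.2% carried a genus name and 99.0% a family name. Bacterial reads per library were 50315 ± 15337 in young vehicle, 37032 ± 16967 in aged vehicle, 7658 ± 7595 in young antibiotics and 25008 ± 6502 in aged antibiotics mice (mean ± SD, n = 3), and 69772 in the Standard library. The shallowest library had 2703 bacterial reads, where a count of 0 allows up to 0.111% (3 reads). ASVs were used as deposited, although 93.4% of them carried primer bases at both ends, with up to 37 ASVs per trimmed sequence; 2658 ASVs came down to 967 trimmed sequences.

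Counts were summed per genus and per family, with taxa lacking a name kept under the lowest named rank. Taxa with at least 10 reads in at least 3 of the fitted libraries were tested with edgeR 4.0.16 (quasi-likelihood F test, library size equal to the bacterial reads, normalization factors 1) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Antibiotics were compared with vehicle over both ages, in each age and for the difference between ages in a model of all 12 fecal libraries, and age was compared in the 6 vehicle and the 6 antibiotics libraries separately. Log2 fold changes are given with a standard error taken as the fold change over the square root of F. Where a group had no read, the fold change is a bound against 3 reads per library, as a share of all bacterial reads, Ralstonia included.

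Richness (expected ASVs at 2703 reads), the Shannon index (natural log), bacterial reads, phylum shares and list shares were tested by two-sided exact permutation of the mean difference, within ages for antibiotics and within treatments for age (400 assignments, smallest p 0.005), or over the 10 splits of 2 groups (smallest p 0.1). Community composition was tested by the pseudo-F of a partition of Bray-Curtis distances, by exact permutation with the same assignments. Scripts were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

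Fixed lists of taxa were Bacteroidales families, Clostridia families, Erysipelotrichia families, butyrate producer genera, lactic acid and bifidobacteria genera, mucin users, sulfite and sulfate reducers, aerotolerant opportunist families, small-intestine genera, diet-borne reads (chloroplast and Lactococcus), host or eukaryote reads (mitochondria), reagent contaminant genera and genera of a common mock community. Taxa are named by a fixed rule: per comparison up to 10 genera higher and 10 lower that pass without overlap between groups, by largest fold change; members of the lists; the 5 largest genera, families and phyla of each group; the most abundant ASV of each group; and for ASV tests the 2 with the smallest p in each direction. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except for 3 alternatives chosen after seeing the data, namely trimming primer bases, removal of Ralstonia reads and limma voom without a block. Permutation tests of shares for the difference between ages, and of list shares for age within treatments in place of the 10 splits within each treatment, were also added after the data were seen. Names outside the rule, such as Akkermansia and Muribaculaceae where they did not pass, belong to the lists.

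Alternatives to the edgeR fit were TMMwsp factors, DESeq2 1.42.0 with poscounts factors, limma 3.58.1 on centred log-ratios (pseudocount 0.5), limma voom with the label number as a random block, no filter, a filter of at least 50 reads in 3 libraries, other sets of libraries in the fit, all ASVs, removal of ASVs seen in the Standard library, and leaving out each mouse in turn. TMMwsp factors ranged from 0.0302 to 3.38 over the 12 fecal libraries. For shares they were all reads as denominator and log2 shares with 0.01% added, and for diversity other indices, levels and distances.

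The tests were tested on simulated data with known changes. With the spread of the real libraries, edgeR found 33.3% of genera changed 64-fold over both ages, 0 of 15 changed 16-fold, and none of those changed in young mice alone. With a dispersion of 0.2, between 40.0% and 100% of changed genera were found and at most 3.28% of unchanged ones. The common dispersion of the genera over the 12 libraries was 3.37, so the rates at 0.2 do not carry over to these data. The simulations were set by spread and fold change. Whether Ralstonia reads, by lowering the other shares, led to false calls was not tested on simulated data. The Standard library entered no comparison. Data on the brain immune cells belong to other parts of the study and were not analysed here.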

Results

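The bacteria of fecal pellets were profiled by sequencing amplicons of the V3/V4 regions of the 16S ribosomal RNA gene. The pellets came from 12 female C57BL/6 mice in 4 groups of 3, namely young mice of 12 weeks and aged mice of 72 weeks, given either vehicle or antibiotics that deplete the gut community. A further library, labelled Standard, belonged to none of these groups. The microbiota profiles accompany a study of how the gut community shapes immune cells of the aged mouse brain. The comparisons address how the makeup of the community differed with antibiotics at each age and with age alone. Bacterial load was not measured, so shares cannot show how far antibiotics depleted the community. Taxa said to rise or fall did so in share, and a taxon can gain share when others are lost. Deposited reads per library ranged from 38242 to 67616 in young vehicle mice, from 17548 to 48513 in aged vehicle mice, from 9387 to 21771 in young antibiotics mice and from 22642 to 34623 in aged antibiotics mice. After organelle and unassigned reads were removed, bacterial reads ranged from 2703 in young antibiotics mouse 2 to 67569 in young vehicle mouse 1. All shares below are in percent of these bacterial reads unless another denominator is named, values are mean ± SD over the 3 mice of a group, and intervals and detection limits cover counting error only.

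In young vehicle mice Bacteroides, which breaks down dietary and host polysaccharides, had the largest mean share, 38.1% ± 36.0 (SD, n = 3), which rested on mouse 1 (79.6%, against 18.3% and 16.3%). In mice 2 and 3 unassigned Muribaculaceae, of the main Bacteroidales family of mice, were larger, at 24.5% and 20.5% (mean of the group 15.0% ± 13.1). Akkermansia, a mucin degrader, stood at 15.2% ± 7.61, Alistipes at 4.80% ± 5.41 and Turicibacter at 4.54% ± 7.87. The largest mean shares of aged vehicle mice were those of the lactic acid producer Lactobacillus at 31.7% ± 11.1, unassigned Muribaculaceae at 20.3% ± 6.93, the Lachnospiraceae NK4A136 group at 6.42% ± 2.05, other Lachnospiraceae without a genus name at 5.52% ± 1.47 and Bacteroides at 5.39% ± 3.84. In young antibiotics mice the largest shares were those of Ralstonia, a bacterium of water and soil that is also a frequent contaminant of DNA reagents, at 27.9% ± 48.3, and of Lactobacillus at 24.9% ± 17.7. The plant-associated genus Curtobacterium stood at 6.28% ± 4.21, the skin genus Staphylococcus at 4.24% ± 2.87 and Streptococcus at 2.51% ± 2.59 in this group. Ralstonia took 83.6% of the bacterial reads of young antibiotics mouse 1 and no read in the other mice of that group, where a count of 0 allows up to 0.111% and 0.0775%. In aged antibiotics mice Ralstonia took 87.2% ± 10.8, Lactobacillus 5.09% ± 3.43, Enterococcus 1.49% ± 1.65, Curtobacterium 1.03% ± 0.936 and Staphylococcus 0.623% ± 0.563. Vehicle mice held Ralstonia too, between 0.0619% and 0.296% of their bacterial reads.

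**Figure D1:**
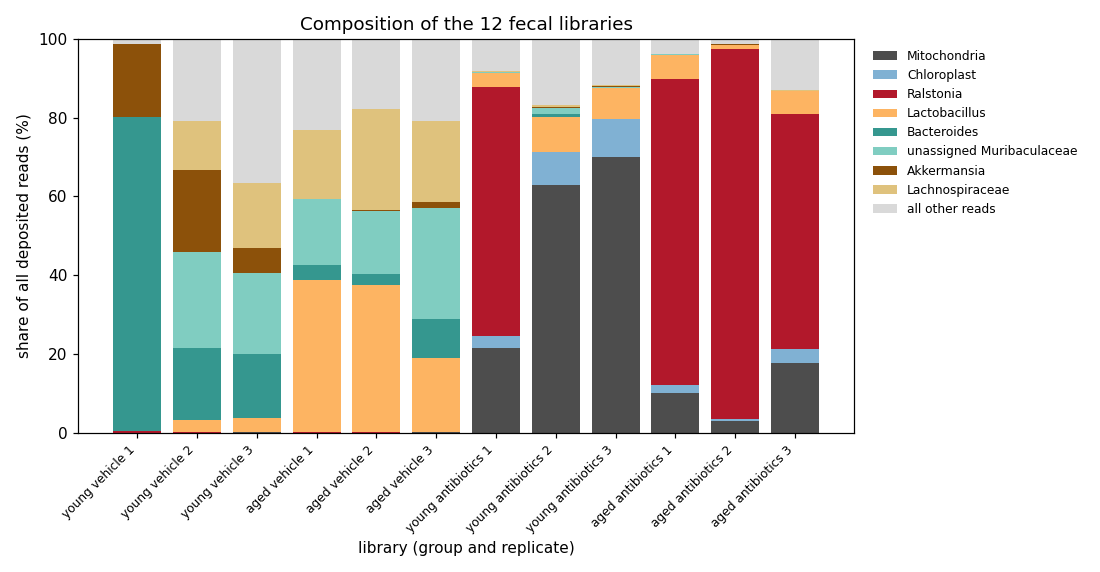
Share of all deposited reads (%) in each of the 12 fecal libraries, split into the largest genera and families and the 2 kinds of organelle reads, with each bar a mouse. Ralstonia fills 4 of the 6 antibiotics libraries, and mitochondrial reads reach 70.0% in young antibiotics mouse 3.

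Antibiotics changed 3 of 5 phyla in the test pooled within ages, and no phylum passed in either age alone, where p cannot fall under 0.1 (exact permutation). Bacteroidota fell from 57.9% ± 20.2 to 3.29% ± 4.02 in young mice and from 30.8% ± 9.18 to 0.184% ± 0.0819 in aged mice. Proteobacteria, of which Ralstonia was the largest genus, rose from 0.568% ± 0.150 to 34.3% ± 43.4 in young mice and from 0.123% ± 0.0995 to 88.2% ± 9.57 in aged mice. Verrucomicrobiota, whose reads here were Akkermansia, fell from 15.2% ± 7.61 to 0.722% ± 0.539 and from 0.629% ± 0.664 to 0.0237% ± 0.0410. Each of these 3 phyla gave p = 0.005 in a two-sided exact permutation test within ages, the smallest that the 400 assignments allow, and an adjusted p of 0.00833 over 5 phyla. Without Ralstonia reads the test for Verrucomicrobiota missed the threshold (adjusted p = 0.055, exact permutation), as it did without any 1 of the 3 young antibiotics mice. Firmicutes stood at 23.8% ± 22.2 and 48.8% ± 31.3 in young and at 62.8% ± 9.07 and 9.02% ± 7.03 in aged mice, vehicle first, with an adjusted p of 0.425 (exact permutation). In percent of reads without Ralstonia, Firmicutes were 27.5 points higher with antibiotics (adjusted p = 0.025, exact permutation), and in percent of all reads they were lower (difference of means -32.5 points, adjusted p = 0.0375). Actinobacteriota gave an adjusted p of 0.419 (exact permutation), and 0.00833 without Ralstonia, when they were 13.1 points higher.

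Organelle reads marked the antibiotics libraries as well. Mitochondrial reads made up 51.5% ± 26.2 (SD, n = 3) of all deposited reads in young and 10.2% ± 7.29 in aged antibiotics mice, against 0.0599% ± 0.0301 and 0.0403% ± 0.0389 in the vehicle mice of the same ages. Chloroplast reads made up 6.99% ± 3.50 and 2.07% ± 1.61, against 0 reads in young vehicle mice and 0.0226% ± 0.0228 in aged vehicle mice. Both gave p = 0.005 in the two-sided exact permutation test within ages. Bacterial reads were 41.5% ± 29.7 of the deposited reads in young and 87.7% ± 8.91 in aged antibiotics mice.

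Over both ages, Bacteroides fell to a mean share 44.9-fold lower, or 23.5-fold without young vehicle mouse 1 (log2 fold change -5.70 ± 1.45, edgeR adjusted p = 0.00116). It was the only genus that fell with no overlap between the antibiotics and the vehicle mice of both ages. The fold and the lack of overlap rest on shares that count Ralstonia reads. Aged antibiotics mouse 2 held 724 reads outside Ralstonia, and its Bacteroides share of these lay above that of aged vehicle mouse 2. Curtobacterium (adjusted p = 0.000389) and the leaf-dwelling Methylobacterium-Methylorubrum (adjusted p = 0.00116), both without a read in aged vehicle mice, and Staphylococcus (log2 6.76 ± 2.18, adjusted p = 0.0043) rose with no overlap. Bacillus, a spore former, was at least 29.1-fold higher and the plant-associated Xanthomonas at least 26.1-fold higher, both without a read in vehicle mice. In all, 64 of 76 genera passed edgeR's quasi-likelihood test, 22 higher and 42 lower with antibiotics, and 6 of them did not overlap between treatments. With TMMwsp factors, which shifted the median log2 fold change of the genera by 1.18 in this comparison, 24 genera were higher and 27 lower, and without Ralstonia reads 24 and 29.

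Bacteroidales families and most Clostridia families fell over both ages. All 3 of the tested Bacteroidales families were lower, Muribaculaceae (log2 -5.30 ± 1.42, adjusted p = 0.000703), Bacteroidaceae (-5.70 ± 1.40, adjusted p = 0.000343) and Rikenellaceae (-6.78 ± 1.91, adjusted p = 0.00105), and all 3 passed when adjusted over the list alone. Of 9 Clostridia families 6 were lower, also 6 when adjusted over the list alone, among them the short-chain fatty acid producers Lachnospiraceae (-5.19 ± 1.46), Oscillospiraceae (-8.06 ± 2.09) and Ruminococcaceae (-5.55 ± 1.85), but Butyricicoccaceae and Peptococcaceae did not pass without Ralstonia reads (adjusted p = 0.0782 and 0.0741). All 5 butyrate producer genera fell, 5 of 5 when adjusted over the list alone, with Roseburia at least 11.0-fold and Intestinimonas at least 11.8-fold lower and no read of either in antibiotics mice. Anaerotruncus and Butyricicoccus missed the threshold with TMMwsp factors (adjusted p = 0.121 and 0.156) and without Ralstonia reads. Both mucin users fell, Bacteroides and Akkermansia (-4.55 ± 1.61, adjusted p = 0.00816), and both when adjusted over the list alone, although the genus Akkermansia missed the threshold with TMMwsp factors (-1.83, adjusted p = 0.201) and without Ralstonia reads (-1.81, adjusted p = 0.172). Its family Akkermansiaceae passed with TMMwsp factors fitted over families (-4.61, adjusted p = 0.00257), DESeq2 (-5.37) and centred log-ratios (-6.60), and missed it without Ralstonia reads (-1.82, adjusted p = 0.174). Of the Erysipelotrichia families Erysipelatoclostridiaceae fell (1 of 2, and 1 when adjusted over the list alone). The 4 tested families of aerotolerant opportunists all rose, 4 when adjusted over the list alone, with Streptococcaceae from 0.00148% to 2.81% in young mice and from no read to 0.291% in aged mice (adjusted p = 5.4e-05), Staphylococcaceae at log2 6.71 ± 1.94, Enterococcaceae at 3.76 ± 1.67 (adjusted p = 0.138 by centred log-ratios) and Xanthomonadaceae at least 29.0-fold higher. The 3 tested reagent contaminant genera, Ralstonia (8.91 ± 1.47), Methylobacterium-Methylorubrum and Corynebacterium (at least 61.6-fold), rose, and 3 did when adjusted over the list alone. Young antibiotics mice 2 and 3 held no Ralstonia read. Of the 4 tested mock community genera Bacillus and Staphylococcus rose (2 when adjusted over the list alone). Neither of the 2 lactic acid and bifidobacteria genera and neither of the 2 small-intestine genera passed (0 when adjusted over the list alone), and no sulfate reducer was seen. Family tests called 20 higher and 15 lower of 45, and with limma on centred log-ratios 17 higher and 20 lower.

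Of the summed shares of the 13 lists 8 passed the exact permutation test within ages. Bacteroidales families, mucin users, aerotolerant opportunists, reagent contaminants, the diet-borne list and the organelle reads each had an adjusted p of 0.0108, and Clostridia families and butyrate producers 0.0325. Clostridia families fell from 14.3% ± 13.0 to 3.23% ± 2.99 in young and from 26.3% ± 4.62 to 0.341% ± 0.366 in aged mice, but passed neither on the log scale (adjusted p = 0.219) nor without young vehicle mouse 3 (adjusted p = 0.065), both exact permutation tests. Lactic acid and bifidobacteria genera (adjusted p = 0.798), mock community genera (0.861), Erysipelotrichia (0.506), small-intestine genera (0.715) and sulfate reducers (1, with no read) did not pass this exact permutation test. Without Ralstonia reads mock community genera were 38.5 points higher with antibiotics (adjusted p = 0.0108, exact permutation). Without young vehicle mouse 3 the count of lists past the threshold was 3. Mucin users did not pass without any 1 of the young antibiotics mice, nor mitochondrial reads without any 1 of the young vehicle mice (adjusted p up to 0.114 and 0.065, exact permutation).

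In young mice alone, antibiotics lowered Bacteroides from 38.1% ± 36.0 to 0.881% ± 0.941, a 43.2-fold lower mean share, or 19.6-fold without young vehicle mouse 1 (log2 -5.44 ± 2.03, edgeR adjusted p = 0.0354). Curtobacterium rose from 0.00443% ± 0.00767 to 6.28% ± 4.21 (log2 10.35 ± 3.40, adjusted p = 0.0331) and Methylobacterium-Methylorubrum from 0.000987% ± 0.00171 to 1.69% ± 1.74 (10.14 ± 3.75, adjusted p = 0.0354). Genera of soil, plants and skin with no read in young vehicle mice rose too, each with an adjusted p of 0.0331. The spore former Paenibacillus was at least 261-fold, Corynebacterium at least 148-fold, Ochrobactrum at least 98.1-fold and unassigned Pseudonocardiaceae at least 67.7-fold higher. Rhodococcus was at least 66.3-fold, Xanthomonas at least 58.1-fold, Bacillus at least 53.0-fold and Kineococcus at least 49.1-fold higher. Ralstonia passed the test as well (7.56 ± 1.96, adjusted p = 0.011), carried by 1 of the 3 mice, and its fold change was -0.50 by centred log-ratios. Muribaculaceae stood at 15.0% ± 13.1 and 2.16% ± 2.66 (adjusted p = 0.178) and Akkermansia at 15.2% ± 7.61 and 0.722% ± 0.539 (adjusted p = 0.112).

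By list, 1 of 3 Bacteroidales families fell in young mice (Bacteroidaceae, 1 when adjusted over the list alone) and 1 of 9 Clostridia families (Oscillospiraceae, -8.20 ± 3.01, adjusted p = 0.0184; 0 when adjusted over the list alone). Of 4 opportunist families 3 rose, Streptococcaceae (10.56 ± 3.12), Staphylococcaceae (6.09 ± 2.67, but adjusted p = 0.142 with TMMwsp factors) and Xanthomonadaceae (at least 60.1-fold), and 3 when adjusted over the list alone. All 3 reagent contaminant genera passed as higher (3 when adjusted over the list alone), but Ralstonia through 1 of the 3 mice, as the others held no read of it. Of the mucin users 1 of 2 fell (1 when adjusted over the list alone) and 1 of 4 mock community genera rose (1 when adjusted over the list alone). None of the 5 butyrate producers, 2 Erysipelotrichia families, 2 lactic acid genera or 2 small-intestine genera passed edgeR's test (0 when adjusted over the list alone). Of 76 genera 18 passed, 17 higher and 1 lower, where TMMwsp factors (median shift 0.61) gave 19 and 5, DESeq2 14 and 13 and centred log-ratios 17 and 16. Of the 17 genera without overlap between the 2 young groups 12 were among the calls, and chance would give 10% of genera. The count fell to 0 without young vehicle mouse 2 or 3 or young antibiotics mouse 2 or 3, and was 29 without young vehicle mouse 1. Of 45 families 21 passed, 18 higher and 3 lower, against 17 and 6 with TMMwsp factors, 14 and 10 with DESeq2 and 12 and 12 with centred log-ratios; the count was 0 without young vehicle mouse 2 and 13 without young antibiotics mouse 3.

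In aged mice several Clostridia genera had no read left with antibiotics, among them the butyrate producers Roseburia and Intestinimonas. Lachnoclostridium was at least 135-fold lower, from 1.71% ± 1.15 to no read, and the [Eubacterium] ventriosum group at least 131-fold lower, from 1.65% ± 0.779. Unassigned Oscillospiraceae were at least 87.0-fold, unassigned Ruminococcaceae at least 61.5-fold, Roseburia at least 51.7-fold, Lachnospiraceae UCG-006 at least 42.2-fold and Intestinimonas at least 40.8-fold lower. The [Eubacterium] xylanophilum group was at least 38.5-fold, the unassigned Clostridia vadinBB60 group at least 37.0-fold and Acetatifactor at least 32.5-fold lower, each of these 10 with an edgeR adjusted p of 0.0305. The bounds of these 10 genera count Ralstonia reads in the library size. Outside Ralstonia the aged antibiotics mice had 3544, 724 and 4299 reads, on which the bounds would be far lower. Unassigned Muribaculaceae fell from 20.3% ± 6.93 to 0.0899% ± 0.0811 (log2 -7.81 ± 2.32, adjusted p = 0.0302) and Alistipes from 5.11% ± 1.61 to 0.00766% ± 0.0133 (-9.26 ± 3.10, adjusted p = 0.0305). Both genera missed the threshold with TMMwsp factors (adjusted p = 0.130 and 0.106). Ralstonia rose from 0.0701% ± 0.00912 to 87.2% ± 10.8 (10.27 ± 2.18, adjusted p = 0.000325). Curtobacterium was at least 104-fold, Streptococcus at least 27.3-fold, Methylobacterium-Methylorubrum at least 24.8-fold, Bacillus at least 13.9-fold and Xanthomonas at least 5.82-fold higher, and Staphylococcus rose by log2 7.17 ± 3.14 (adjusted p = 0.044).

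By list, all 3 Bacteroidales families fell in aged mice (3 when adjusted over the list alone), among them Muribaculaceae (-7.81 ± 2.25, adjusted p = 0.00879), but Bacteroidaceae did not pass without Ralstonia reads (adjusted p = 0.179). Of 9 Clostridia families 6 fell (6 when adjusted over the list alone), among them Lachnospiraceae, from 21.2% ± 4.19 to 0.144% ± 0.175 (-7.20 ± 2.26, adjusted p = 0.0118). Without Ralstonia reads Anaerovoracaceae (adjusted p = 0.129), Butyricicoccaceae (0.162), Monoglobaceae (0.158) and Ruminococcaceae (0.0696) missed the threshold. Of 5 butyrate producers 2 fell, Roseburia and Intestinimonas (2 when adjusted over the list alone), and of 2 Erysipelotrichia families 1 fell, though not without Ralstonia reads (0 when adjusted over the list alone). All 4 opportunist families rose (4 when adjusted over the list alone), as did all 3 reagent contaminant genera (3 when adjusted over the list alone) and 2 of 4 mock community genera (2 when adjusted over the list alone). Of the mucin users Bacteroides fell (-5.95 ± 2.08, adjusted p = 0.0305) and Akkermansia did not pass (-4.70 ± 2.29, adjusted p = 0.0574) and changed sign with TMMwsp factors (1.91) and without Ralstonia reads (0.42), while 2 passed when adjusted over the list alone; Bacteroides missed the threshold with TMMwsp factors (-0.59, adjusted p = 0.816) and without Ralstonia reads (adjusted p = 0.195). None of the 2 lactic acid genera and 2 small-intestine genera passed edgeR's test (0 when adjusted over the list alone). Of 76 genera 48 passed, 17 higher and 31 lower, and 37 of the 48 genera without overlap between the aged groups were among them, where chance would give 10% of genera. TMMwsp factors (median shift 1.62) gave 23 higher and 4 lower, DESeq2 20 and 24, centred log-ratios 23 and 28 and removal of Ralstonia reads 22 and 6, so the count of lower genera rests on the scaling. Of the 10 lower genera named above only Lachnoclostridium, the [Eubacterium] ventriosum group, unassigned Oscillospiraceae and unassigned Ruminococcaceae passed with TMMwsp factors, and only these without Ralstonia reads. The count fell to between 0 and 4 without any 1 of the 6 aged mice, namely 0, 1 and 0 without vehicle mouse 1, 2 and 3 and 4, 3 and 0 without antibiotics mouse 1, 2 and 3. Of 45 families 30 passed, 16 higher and 14 lower, against 19 and 9 with TMMwsp factors and 20 and 5 without Ralstonia reads, and 9 to 22 passed without 1 of the aged mice.

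Of the taxa that rose, 14 genera passed in both ages, out of 17 in each, where independent lists would share 3.80. Both tests came from the same model with shared estimates of spread, so the lists are not independent. The fold changes of 73 of 76 genera and 44 of 45 families had the same sign in young and aged mice. No genus and no family passed edgeR's test of the difference between ages after adjustment, with 1 genus and 2 families at an unadjusted p under 0.05. DESeq2 called 0 genera and 1 family in that test, centred log-ratios 0 and 0, and limma voom 1 genus, while 1 of 2 lactic acid genera and 1 of 4 mock community genera passed when adjusted over the list alone and no member of the other lists did. In tests of shares added after the data were seen, the largest phylum difference between the ages was that of Firmicutes, 25.0 points higher with antibiotics in young mice against -53.8 points in aged mice (difference -78.8 points, exact permutation p = 0.01, adjusted p = 0.05, not under the threshold). The 8 genera compared by share were Ralstonia, Lactobacillus, Bacteroides, Akkermansia, unassigned Muribaculaceae, Alistipes, Turicibacter and Bifidobacterium. This set was picked by hand and leaves out large genera such as Curtobacterium, Staphylococcus and Enterococcus. Within the set only Lactobacillus lay in opposite directions without overlap. Every young antibiotics mouse lay above every young vehicle mouse and every aged antibiotics mouse below every aged vehicle mouse, a difference of -49.2 points between the effects (two-sided exact permutation p = 0.015, adjusted p = 0.12 over 8 genera). In percent of reads without Ralstonia, Lactobacillus stood at 2.28% ± 1.82 and 33.2% ± 4.52 in young and at 31.7% ± 11.1 and 43.7% ± 15.0 in aged mice, vehicle first, and the difference between the effects was -18.9 points (exact permutation p = 0.27). TMMwsp factors likewise turned its fold change in aged mice from -2.64 to 1.72.

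**Figure D2:**
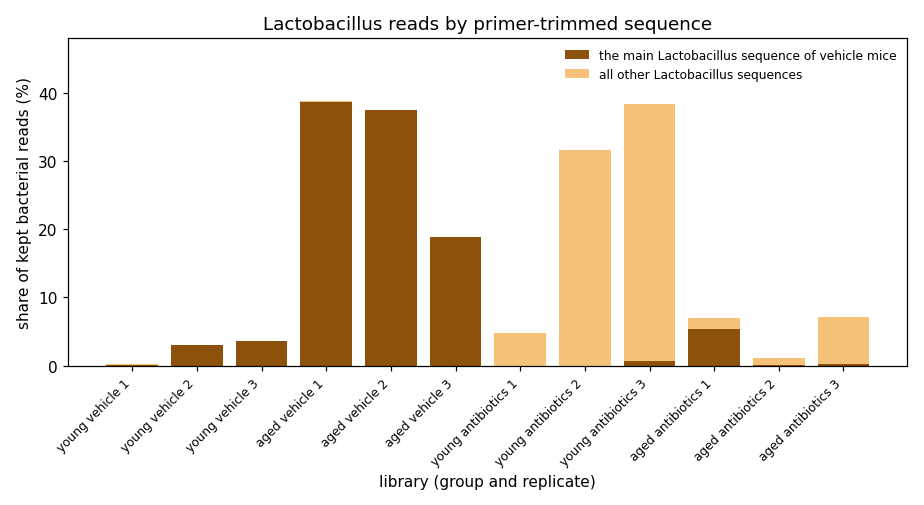
Lactobacillus reads in percent of the bacterial reads of each mouse, split into the sequence that dominated vehicle mice and all other Lactobacillus sequences after trimming of primer bases. The main vehicle sequence takes 31.7% ± 11.1 in aged vehicle mice and 0.233% ± 0.403 in young antibiotics mice.

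The whole community differed between treatments and, less, between ages. Treatment within ages accounted for 38.3% of the variation in Bray-Curtis distance (pseudo-F, exact permutation p = 0.005, the smallest possible) and age within treatments for 13.2% (exact permutation p = 0.01). Young vehicle and young antibiotics mice lay at a mean distance of 0.973 and the aged groups at 0.976, against 0.624 within young vehicle, 0.462 within aged vehicle and 0.193 within aged antibiotics mice, while young antibiotics mice lay nearly as far from each other (0.927) as from vehicle mice. Outside Ralstonia, between 28.9% and 56.7% of the bacterial reads of young and between 34.0% and 77.0% of those of aged antibiotics mice lay in trimmed sequences also seen in vehicle mice. Within single ages or treatments the 10 splits allow no p under 0.1, and the tests gave 38.3% of the variation for antibiotics in young mice, 83.3% in aged mice and 46.0% for age in vehicle mice (exact permutation p = 0.1 for each). Without Ralstonia reads antibiotics gave 42.7% in young and 37.9% in aged mice (exact permutation p = 0.1 for both). Mice of the aged antibiotics group then lay at a mean distance of 0.921 from each other, and young ones at 0.853. The 83.3% and the 0.193 thus rest on Ralstonia reads. Age within treatments missed the threshold at genus level (8.91%, p = 0.21), by Jaccard distance (8.44%, p = 0.14), both exact permutation tests, and without young vehicle mouse 1 or any of the aged antibiotics mice.

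**Figure D3:**
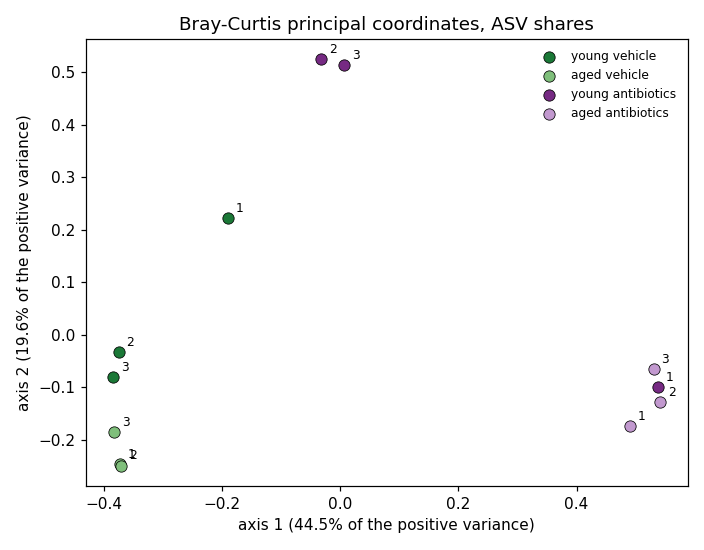
Principal coordinates of the Bray-Curtis distances between the 12 fecal libraries, with each point a mouse numbered within its group; the axes carry 44.5% and 19.6% of the positive variance. The 4 antibiotics mice with Ralstonia lie together, young antibiotics mice 2 and 3 apart from them, and young vehicle mouse 1 apart from the other vehicle mice.

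The mean number of amplicon sequence variants (ASVs, distinct sequences) was lower with antibiotics but did not pass after adjustment. At a common depth of 2703 reads, richness was 333 ± 223 ASVs in young and 474 ± 117 in aged vehicle mice, against 151 ± 26.3 and 140 ± 75.9 with antibiotics (two-sided exact permutation p = 0.02 within ages, adjusted p = 0.075 over 9 tests). The Shannon index stood at 5.12 ± 1.06 and 5.71 ± 0.278 in vehicle mice and at 4.52 ± 0.408 and 4.04 ± 0.409 in antibiotics mice (exact permutation p = 0.025, adjusted p = 0.075). Bacterial reads per library gave the same adjusted p of 0.075 (exact permutation p = 0.02; difference of means -27341). Primer bases left in the sequences split abundant amplicons into several ASVs, although 588 of 967 trimmed sequences had only 1. The richness test was therefore repeated on merged sequences, where p was 0.145 (exact permutation) and the difference -47.5 sequences. In young mice the difference of -182 ASVs shrank to -3.17 merged sequences (exact permutation p = 1), and in aged mice it was -334 ASVs and -91.8 merged sequences (exact permutation p = 0.1 for both). The young difference was -307 ASVs without young vehicle mouse 1, which lay below every young antibiotics mouse, and -92.9 without young vehicle mouse 3. Age did not pass for richness (exact permutation p = 0.49) or the Shannon index (exact permutation p = 0.925).

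Among single ASVs, 385 of 421 passed edgeR's test over both ages, 85 higher and 300 lower. Of these, 32 were without overlap, all of them lower. The smallest p belonged to ASV164 and ASV143 of Ralstonia, at least 60.5-fold and 68.0-fold higher, and to ASV102 and ASV103 of Muribaculaceae, at least 12.0-fold and 12.1-fold lower. In young mice 100 passed, 64 higher and 36 lower, with ASV488 of Lactobacillus and ASV560 of Staphylococcus at least 137-fold and 199-fold higher and ASV36 and ASV75 of Akkermansia at least 22.1-fold and 13.7-fold lower. In aged mice 157 passed, 49 higher and 108 lower, with ASV164 and ASV143 of Ralstonia at least 76.1-fold and 84.9-fold higher and ASV107 and ASV103 of Muribaculaceae at least 45.4-fold and 43.5-fold lower. Once primer bases were trimmed and equal sequences merged, 111 sequences passed over both ages, 0 in young and 2 in aged mice. No ASV passed in young or in aged mice with TMMwsp factors or without Ralstonia reads, none in young mice without young vehicle mouse 2 or 3, and none in aged mice without any 1 aged mouse. Without young vehicle mouse 1 the young calls turned to 7 higher and 98 lower. Centred log-ratios called 94 higher and 125 lower ASVs over both ages and 97 and 118 in aged mice, and DESeq2 called 47 higher and 140 lower in young mice. The test of the difference between ages called 0 ASVs by edgeR, with 17 at an unadjusted p under 0.05, 30 by DESeq2 and 5 by centred log-ratios.

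The most abundant ASV of young vehicle mice, ASV1 of Bacteroides, took 1.98% ± 1.96 of the reads and read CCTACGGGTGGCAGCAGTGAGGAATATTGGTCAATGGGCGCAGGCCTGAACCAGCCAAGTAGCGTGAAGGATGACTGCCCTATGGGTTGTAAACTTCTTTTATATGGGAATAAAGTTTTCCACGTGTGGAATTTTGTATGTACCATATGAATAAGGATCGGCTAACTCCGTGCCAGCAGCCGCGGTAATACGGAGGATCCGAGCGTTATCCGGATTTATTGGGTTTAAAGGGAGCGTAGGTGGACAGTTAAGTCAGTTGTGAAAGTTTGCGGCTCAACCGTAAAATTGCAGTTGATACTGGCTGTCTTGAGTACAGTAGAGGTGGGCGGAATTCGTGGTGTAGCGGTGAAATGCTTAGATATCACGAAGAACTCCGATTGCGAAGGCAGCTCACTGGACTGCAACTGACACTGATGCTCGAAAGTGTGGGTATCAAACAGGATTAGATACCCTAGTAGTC. With the 31 other ASVs that differ from it in primer bases alone it made up 37.1% ± 34.5. In aged vehicle mice ASV54 of Lactobacillus took 1.44% ± 0.381, and 35 ASVs with its trimmed sequence took 31.7% ± 11.1. The most abundant ASVs of antibiotics mice were ASV543 of Lactobacillus at 1.33% ± 1.77 in young mice and ASV5 of Ralstonia at 3.92% ± 0.210 in aged mice. Young and aged vehicle mice shared 398 ASVs, out of 965 and 1273, which took 87.1% ± 7.83 and 81.8% ± 3.35 of their reads. Young vehicle and young antibiotics mice shared 62 ASVs, the aged groups 63, and the antibiotics groups of both ages 125.

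With age alone, in vehicle mice, Akkermansia, the mucin degrader, was at 15.2% ± 7.61 in young and 0.629% ± 0.664 in aged mice (log2 -4.60 ± 1.85, edgeR adjusted p = 0.231). Lactobacillus was at 2.27% ± 1.82 and 31.7% ± 11.1, 13.9-fold higher (3.80 ± 1.37, adjusted p = 0.231). Bacteroides was at 38.1% ± 36.0 and 5.39% ± 3.84 (-2.82 ± 1.20, adjusted p = 0.25), and the fiber degrader Ruminococcus had no read in young mice and 0.189% ± 0.109 in aged mice, at least 29.9-fold more (adjusted p = 0.231). The young and aged mice did not overlap in any of these 4 genera, and 8 of the 51 tested genera showed no overlap, where chance would give 10%. No genus of 51, no family of 25 and no ASV of 318 passed edgeR's test, with 4, 2 and 41 at an unadjusted p under 0.05. On simulated data with the spread of the vehicle libraries, edgeR found 0, 1 and 0 of 10 genera changed 4-fold, 16-fold and 64-fold. Of the changed ASVs it found at most 4.69%, so the lack of calls does not show that age changed nothing. DESeq2 called 3 genera, 2 families and 0 ASVs and centred log-ratios 3, 3 and 18. Limma voom called 0 genera, and 24 (20 higher, 4 lower) with the label number as a random block, whose correlation was -0.743. By Bray-Curtis distance the same-numbered pair of aged vehicle mice was closer than the other pairs of its group (0.332, against 0.534 and 0.520). The same-numbered young pair lay between the others (0.627, against 0.767 and 0.479). The correlation rests on few same-numbered pairs, so it decides nothing about a cage or batch. The 24 calls are therefore not read as an age effect. Akkermansia passed by DESeq2 and by centred log-ratios (adjusted p = 0.0263 for the latter), and Lactobacillus and Ruminococcus by DESeq2. Mucin users passed 2 of 2 when adjusted over the list alone, lactic acid genera 1 of 2 and mock community genera 1 of 2; the other lists passed 0 of their tested members, 3 Bacteroidales, 7 Clostridia and 2 Erysipelotrichia families, 5 butyrate producers, 1 opportunist family and 1 reagent contaminant. The phylum Verrucomicrobiota was lower with age within treatments (exact permutation p = 0.005, adjusted p = 0.025), as were the mucin users and the aerotolerant opportunists (adjusted p = 0.0325 each, exact permutation, a test of lists added after the data were seen). Without Ralstonia reads these adjusted p values were 0.142, 0.179 and 0.91 (exact permutation), and each missed the threshold when any 1 aged mouse was left out. The mucin users and the opportunists also missed it without young antibiotics mouse 2 or 3. With all reads as denominator their adjusted p values were 0.065 and 0.303 (exact permutation).

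With age under antibiotics, Ralstonia stood at 27.9% ± 48.3 in young and 87.2% ± 10.8 in aged mice (log2 1.64 ± 2.86, edgeR adjusted p = 0.719) and Lactobacillus at 24.9% ± 17.7 and 5.09% ± 3.43 (-2.29 ± 2.13, adjusted p = 0.523). Curtobacterium stood at 6.28% ± 4.21 and 1.03% ± 0.936 and Staphylococcus at 4.24% ± 2.87 and 0.623% ± 0.563 (adjusted p = 0.382 for both). The fold changes of Lactobacillus and Curtobacterium changed sign with DESeq2, centred log-ratios and without Ralstonia, and that of Staphylococcus with centred log-ratios (0.03). Unassigned Pseudonocardiaceae came closest to the threshold, at 0.427% ± 0.313 against no read, at least 33.8-fold lower (adjusted p = 0.0697). No genus of 33, no family of 29 and no ASV of 87 passed edgeR's test, with 1, 2 and 0 at an unadjusted p under 0.05. DESeq2 called 1, 0 and 0 and centred log-ratios 0, 0 and 0, and among the lists 1 Erysipelotrichia family of 1 passed when adjusted over the list alone and no other member did. The communities of the antibiotics groups gave 36.0% of the variation for age (exact permutation p = 0.2), and 17.6% without Ralstonia (exact permutation p = 1).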

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

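The tests of the explanations weighed in this part, the counts over other splits and the permutation tests of shares for the difference between ages were chosen after results were seen.

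Lactobacillus stood out because antibiotics moved its share in opposite directions in the 2 ages, with a difference between the effects of -49.2 points (two-sided exact permutation p = 0.015, adjusted p = 0.12 over the 8 genera picked by hand). The genera of a common mock community, of which Lactobacillus is the largest in fecal libraries, stood out in the same way (-53.4 points, exact permutation p = 0.01, adjusted p = 0.0975). Mitochondrial reads stood out as a signal among reads left out of the comparisons, at 51.5% of all reads in young and 10.2% in aged antibiotics mice, as did chloroplast reads at 6.99% and 2.07%, each above the vehicle mice. Ralstonia stood out in the Standard library, which entered no comparison, with 132 reads.

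Ralstonia took most bacterial reads of 4 antibiotics libraries, was absent from young antibiotics mice 2 and 3 and held a low share in all vehicle libraries and the Standard library. In the young group its presence followed the label number, as mouse 1 carried number 1 and mice 2 and 3 carried number 2. Aged antibiotics mice of both label numbers held it at a high share. What the number marks is not known. Reads crossing evenly between libraries were argued against by 0 Bacteroides reads in the Standard library, where the crossing that brought 132 Ralstonia reads would bring 122. A reagent contaminant at a similar share in every library was excluded by the shares themselves, as the lowest of the 4 high libraries held 256 times the highest share of the vehicle and Standard libraries in percent of bacterial reads and 202 times in percent of all reads. In the authors' processing, not all rare sequences of these 2 libraries were lost, as 57 ASVs of at most 5 reads were kept there. This cannot decide whether a few Ralstonia reads were lost. Ralstonia reads made 37 to 42 ASVs in the 4 high libraries but only 1 to 3 in vehicle libraries, so rare variants may go uncounted. A fixed amount in every library stays open. The absence of Ralstonia reads in young antibiotics mice 2 and 3 was far from the 17.6 expected if they held as much template of all kinds as a vehicle mouse (exact one-sided Poisson p = 2.2e-08). It was nearer the 4.07 expected for as much bacterial template (exact one-sided Poisson p = 0.0171). Both p values cover counting error only, while the Ralstonia share varied from 0.0618% to 0.296% of all reads over vehicle and Standard libraries. Template was not measured, and contamination of some libraries, uneven crossing and growth of Ralstonia were not tested.

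In young mice the higher Lactobacillus share was mostly not the Lactobacillus of vehicle mice, as at most 32.9% of the Lactobacillus reads of a young antibiotics library lay in sequences seen in any vehicle library, although these took 10.4% and 10.2% of the bacterial reads of mice 2 and 3, against at most 3.58% in young vehicle mice. The lower share in aged antibiotics mice went with Ralstonia reads in the denominator, since without them the aged antibiotics mean lay 12.0 points above the aged vehicle mean, against -26.6 points with them, which is consistent with Ralstonia lowering every other share. The ratio of mitochondrial to chloroplast reads varied 1.62-fold over the 6 antibiotics libraries while the mitochondrial share varied 23.2-fold, but it parted the ages, at 7.33 ± 0.294 in young and 5.24 ± 0.646 in aged antibiotics mice (two-sided exact permutation p = 0.1, the smallest possible), so a single plant-derived source of both stays open. Where the other Lactobacillus sequences came from was not tested. A biological difference between the ages stays open and was not tested apart from these.

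Young vehicle mouse 1 lay apart from the other vehicle mice, with Bacteroides at 79.6% and a richness of 83.2 ASVs against 404 and 512. A swap with an antibiotics library was argued against by distance, since the closest antibiotics library lay at 0.938 from young vehicle mice 2 and 3 and young vehicle mouse 1 at no more than 0.767. Shallow sequencing was argued against by its 67569 bacterial reads, the most of any fecal library. A wrong label without a partner stays open, and no biological explanation was tested.

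Other splits of the 12 fecal libraries were counted for each test over many taxa, 100 of them for the antibiotics effect over both ages. Only the real split gave as many calls, namely 64 genera (highest other 52), 35 families (18) and 385 ASVs (349), while the median of the other splits was 0. This argues against chance for the total count and decides nothing for any single taxon. The high counts of some other splits point to a structure of the samples. For the difference between ages the real split called 0 genera (highest other 2), 0 families (4) and 0 ASVs (6), and a count of 0 is reached by all 100 splits, so the comparison decides nothing. The 10 splits within an age or a treatment are too few for a share under 0.05. There, in young mice, 1 split, the real one, gave 18 genera (highest other 0), 21 families (1) and 100 ASVs (0), and in aged mice 48 genera (0), 30 families (0) and 157 ASVs (0). For age the real count was 0 throughout, with a highest other of 4 genera, 0 families and 0 ASVs in vehicle mice and of 1 genus, 11 families and 9 ASVs in antibiotics mice, where 11 families from a split other than age point to a structure of the samples.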

How the results depend on the processing

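The alternatives with primer bases trimmed, without Ralstonia reads and with limma voom without a block were chosen after the results were seen, and the others were planned. Of the alternative values for counts of taxa, 48 of 64 at genus level, 44 of 52 at family level and 39 of 58 at ASV level stayed within 1.5-fold of the edgeR count, leave-one-out apart. For the values below that moved, the cause was not tested unless it is named.

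Genera past the threshold over both ages were 64, and 32 with at least 50 reads in 3 samples, where fewer genera were tested. In young mice 18 genera passed, against 33 with limma on centred log-ratios, 0 with no filter, 0 with at least 50 reads in 3 samples, 7 with only the groups compared and 31 with all ASVs kept. In aged mice 48 passed, against 27 with TMMwsp factors, 0 with no filter, 27 with at least 50 reads in 3 samples and 28 without Ralstonia. For the difference between ages edgeR called 0, limma voom 1 and limma voom with the label number as a random block 4. For age in vehicle mice edgeR called 0, DESeq2 3, centred log-ratios 3 and voom with the block 24, at a block correlation of -0.743. For age in antibiotics mice edgeR called 0 and DESeq2 1.

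Families past the threshold over both ages were 35, and 18 with at least 50 reads. In young mice 21 passed, 5 with at least 50 reads and 10 with only the groups compared, and in aged mice 30 passed, 10 with no filter and 17 with at least 50 reads. For the difference between ages edgeR called 0 and DESeq2 1, and for age in vehicle mice edgeR 0, DESeq2 2 and centred log-ratios 3. ASVs past the threshold over both ages were 385, and 219 with centred log-ratios, 160 with no filter, 215 with at least 50 reads, 176 without Ralstonia and 111 with primer bases trimmed. In young mice 100 ASVs passed, 0 with TMMwsp factors, 187 with DESeq2, 0 with no filter, 60 with only the groups compared, 233 with all ASVs kept, 0 without Ralstonia and 0 with primer bases trimmed. In aged mice 157 passed, 0 with TMMwsp factors, 0 with no filter, 0 without Ralstonia and 2 with primer bases trimmed. For the difference between ages DESeq2 called 30 ASVs and centred log-ratios 5, and for age in vehicle mice centred log-ratios 18, each against 0 by edgeR.

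The share of lactic acid and bifidobacteria genera turned from 4.48 points lower with antibiotics to 19.97 points higher without Ralstonia (adjusted p = 0.0325, exact permutation), and Firmicutes from 14.4 points lower to 27.5 points higher (adjusted p = 0.025, exact permutation), by the removal of those reads from the denominator. The difference of the antibiotics effect on bacterial reads between ages was 30633 (exact permutation p = 0.045, adjusted p = 0.101) and 24859 in all deposited reads (p = 0.095). The richness difference with antibiotics was -258 ASVs and, with primer bases trimmed, -47.5 (exact permutation p = 0.145), where fewer sequences were counted. The Shannon difference was -1.14, and -0.715 at genus level (p = 0.26), -0.835 with primer bases trimmed (p = 0.31) and -0.926 without Ralstonia (p = 0.055), all exact permutation tests. In young mice alone the Shannon difference of -0.604 turned to 0.302 at genus level and 0.591 with primer bases trimmed (exact permutation p = 0.5 for both), against -1.73 and -2.26 in aged mice (p = 0.1 for both). The richness difference in young mice went from -182 ASVs to -3.17 trimmed sequences. Age within treatments took 13.2% of the Bray-Curtis variation, 8.44% by Jaccard distance and 8.91% at genus level (exact permutation p = 0.14 and 0.21). The antibiotics effect on composition kept its direction and its side of the threshold throughout.

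Leaving out each mouse in turn gave 48 to 65 genera over both ages, 0 to 29 in young mice, 0 to 4 in aged mice, 0 to 2 for the difference between ages, 0 to 3 for age in vehicle mice and 0 to 2 for age in antibiotics mice. Families ranged from 29 to 39, 0 to 25, 9 to 22, 0 to 2, 0 to 3 and 0 to 3 in that order, and ASVs from 151 to 372, 0 to 105, 0 to 0, 0 to 0, 0 to 43 and 0 to 37. Lists past the threshold ranged from 3 to 8 and phyla from 2 to 3. The Shannon difference with antibiotics ranged from -1.44 to -0.934 and the difference of that effect between ages from -1.47 to -0.460. The richness difference ranged from -321 to -214. Treatment took 35.5% to 46.4% of the Bray-Curtis variation and age 11.7% to 19.9%. The counts of genera and ASVs in aged mice fell without any 1 of the 6 aged mice, and a fit with fewer mice has less power by construction.

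No paired analysis was possible because the label numbers 1 and 2 repeat within a group and the replicate numbers, given in accession order, pair nothing across groups. With the label number as a random block within groups, limma voom called 54 genera over both ages (block correlation -0.0979), 24 for age in vehicle mice (-0.743) and 0 for age in antibiotics mice (0.271). The negative correlation in vehicle mice rests on few same-numbered pairs and decides nothing about a cage or batch, so the 24 calls are not read as an age effect. By all bacterial reads, depth limits the young antibiotics mice most, since 2703 reads leave taxa under 0.111% unseen. Outside Ralstonia the fewest reads were those of aged antibiotics mouse 2, at 724, against 2687, 2703 and 3869 in young antibiotics mice. Absence of a taxon is therefore not better shown in aged than in young antibiotics mice.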

Other observations

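The tests in this part, on Lactobacillus sequences and on label numbers, were chosen after the results were seen.

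Most Lactobacillus reads of young antibiotics mice lay in sequences that no vehicle mouse carried, and the aged antibiotics mice varied. After trimming of primer bases, a single sequence held 99.8% of the 36407 Lactobacillus reads of vehicle mice, at 2.26% ± 1.84 of bacterial reads in young and 31.7% ± 11.1 in aged vehicle mice (mean ± SD, n = 3). That sequence was at 0.233% ± 0.403 in young and 1.92% ± 2.97 in aged antibiotics mice. In aged antibiotics mice 1, 2 and 3 it held 77.1%, 10.3% and 4.13% of the Lactobacillus reads, and sequences seen in any vehicle mouse held 85.9%, 42.4% and 28.5%, against 18.2%, 32.9% and 26.7% in young antibiotics mice. Lactobacillus sequences without a read in vehicle mice took 17.7% ± 12.4 in young and 2.26% ± 2.51 in aged antibiotics mice, and were picked for having no vehicle read, so they were not tested. There were 45 such sequences, 12 of them in both ages, and 4 of the 5 Lactobacillus sequences found in every antibiotics library had no vehicle read.

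The Standard library held 69772 bacterial reads, with Staphylococcus at 19.9% (95% Wilson interval 19.6 to 20.2), Listeria at 18.2%, Lactobacillus at 14.8%, Bacillus at 12.8% and Enterococcus at 10.3%. Escherichia-Shigella followed at 9.68%, Salmonella at 7.78%, Pseudomonas at 4.43%, unassigned Enterobacteriaceae at 1.87% and Ralstonia at 0.189%. Its 271 ASVs came down to 21 trimmed sequences. Listeria, Salmonella, Escherichia-Shigella and unassigned Enterobacteriaceae held 26184 of its reads and 0 of the 360038 bacterial reads of fecal libraries (upper limit 0.000833%). No fecal Lactobacillus read lay in a Lactobacillus sequence of the Standard library.

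Mice of a group whose labels share a number lay at a mean Bray-Curtis distance of 0.509, against 0.573 for other mice of a group, and were closer in 2 of 4 groups. The test that same-numbered mice lie closer did not pass (exact one-sided permutation p = 0.173 over 81 placements), which leaves open whether the number marks a cage or a batch.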
